A study of Mus musculus with 36 samples.

How the data were processed

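RNA sequencing was done on 36 libraries of mouse bone-marrow-derived dendritic cells, WT or KO for LGP2, mock treated or transfected with 20 ng of PAMP RNA, at 1, 3 and 6 h, with 3 libraries in each of 12 groups. Libraries were made with a SMARTer kit and Nextera XT, which do not mark the strand, and read as single reads on an Illumina HiSeq. Per the labels, the submitters' processing used TopHat, Cufflinks and DESeq2 with the mouse genome GRCm38 (mm10). Versions, the role of each tool, the gene annotation and any filter are not given in the sources used here. The deposited values are a signal per gene, DESeq-normalized read counts that the authors obtained by dividing the reads of a gene by 1 size factor per library.

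The table held 24127 genes, of which 4887 had no read, with 0 duplicated genes and 0 unmapped columns. In each library all values (100%) were whole multiples of the smallest step within a tolerance of 0.01 read, so whole reads were recovered by dividing by that step. The recovered totals were 4740909 to 14255730 reads per library. The 10 most abundant genes took 8.30% to 10.4% of a library's normalized counts. The lowest Pearson correlation between libraries of a group was 0.989 on the log2 scale. The chi-square per degree of freedom between libraries of a group was 1.33 to 6.32, and the biological coefficient of variation from edgeR was 4.5%.

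Values were used on the scale log2(normalized count + 1), for the 11853 genes with a mean normalized count of at least 10. A fold on this scale understates the change of genes with low counts. The main test was limma with a mean-variance trend (version 3.58.1, R 4.3.3), fitted to the 12 group means with 24 residual degrees of freedom. All p-values of single genes are two-sided and Benjamini-Hochberg adjusted over the genes tested, and a gene was called at an adjusted p under 0.05. Responses are PAMP RNA minus mock at the same time and genotype. The 13 tests were the 6 responses, the KO response minus the WT response at each time and over all times at once, KO minus WT in mock cells averaged over time, and the response at 6 h minus that at 3 h in each genotype. Responses of 1 genotype at different times have their own controls, while the genotype differences reuse the libraries of both responses. Unless said otherwise, changes are given in log2 units.

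Of 33 gene lists fixed before the data were examined, 29 had at least 5 tested genes and were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. A median given without a further p passed camera at both settings or has its p beside it in the same or next sentence. Adjusted p-values of lists are over the lists of a comparison. The mean of each list per library was also compared between genotypes by an exact permutation test over 400 relabellings of the libraries within treatment, and again once the mean genotype difference over both treatments was removed. A list of hypoxia-inducible genes was added after seeing the data, and its medians are given without a p-value.

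The genes named follow a rule written before the data were examined. They are Dhx58 in every group, a panel of 27 genes of RNA sensing and interferon response in every response, and in each comparison up to 10 genes with the largest rise and 10 with the largest fall. Those had to pass the test, have a mean normalized count of at least 50 and, for responses, libraries of the groups that did not overlap (10% of genes by chance for 3 against 3). Up to 4 members of each list described were added. Of the panel, Ifnl2 had 0 reads and Ifnl3 had 2 reads in all libraries and neither was tested. The values of 1 gene of the panel are not reported here. Positions are from the GENCODE annotation of GRCm38.

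Where no mock library held a read, a fold is given against a floor of 3 reads over the group. With 1 to 3 mock reads the ratio is given with an exact 95% binomial interval. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Fitted changes of such genes depend on the pseudocount.

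The numbers of the replicates did not pair the libraries: residuals of libraries with the same number correlated at a median of 0 (from -0.11 to 0.10) and 8 of 36 libraries lay closest to one of their own number. The p-values measure the spread between these libraries, and whether the 3 of a group are separate mice, cultures or wells is not given in the sources used here.

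The test was checked on simulated data with the spread of these libraries. Of genes changed 1.25-fold, 1.5-fold, 2-fold and 4-fold in WT cells at 6 h, limma called 54%, 92%, 92% and 100%, and for the genotype difference at 6 h 26%, 64%, 86% and 98%. Of unchanged genes limma called 14 and 8, edgeR 7 and 3, and DESeq2 7 and 7. Simulated reads were recovered in 100% of values. edgeR (version 4.0.16) and DESeq2 (version 1.42.0) were run on the recovered reads as alternatives. edgeR called 103, 5357 and 7640 genes in WT and 156, 6033 and 8364 in KO cells at 1, 3 and 6 h, 9, 423 and 1156 for the genotype difference in response and 2889 in mock cells. Other alternatives were pseudocounts of 0.5 and 8, a filter at a mean of 50 or at detection only, TMM and quantile normalization, only the libraries compared, array weights, a replicate block, a minimum change of 2-fold and leaving out each library. Scaling to equal total reads was added after seeing the data. Normalized totals rose with PAMP RNA, to group means of 9.62 M (M for mega) in WT and 10.36 M in KO cells at 6 h against 7.43 M and 7.40 M in mock cells. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.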

Results

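Gene expression was measured by RNA sequencing in mouse dendritic cells grown from bone marrow with GM-CSF and purified by CD11c, an integrin on the surface of dendritic cells. The cells came from wild-type (WT) mice or from mice labelled as lacking LGP2 (here KO), an RNA-binding helicase encoded by Dhx58 and related to the RNA sensors RIG-I and MDA5. They were transfected with 20 ng of PAMP RNA, the poly-U/UC stretch of the hepatitis C virus genome that RIG-I binds, or served as mock controls. RNA was collected after 1, 3 or 6 h. Each of the 12 combinations of genotype, treatment and time held 3 libraries, 36 in all. The libraries held 4740909 to 14255730 reads in genes and detected 14371 to 15417 genes each. The labels call the control cells both mock and untreated, so a response is the difference between PAMP RNA and these cells, with whatever the transfection itself contributed. The first principal component of the 36 libraries held 63.1% of the variance and the second 15.1%.

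Dhx58, the gene targeted in KO mice, lies on chromosome 11 from 100694884 to 100704271 on the minus strand of GRCm38. In WT cells its normalized count was 93.6 ± 9.71 (SD, n = 3) in mock cells and 98.3 ± 6.59 with PAMP RNA at 1 h, 132 ± 14.8 and 1477 ± 61.7 at 3 h, and 307 ± 47.6 and 3005 ± 62.9 at 6 h. The WT response was 0.07 (SE 0.14, adjusted p = 0.947), 3.48 (SE 0.14, adjusted p = 1.69e-26) and 3.30 (SE 0.14, adjusted p = 8.96e-26) on the log2 scale. KO cells held Dhx58 reads as well, with 147 ± 58.3, 451 ± 71.7 and 722 ± 87.3 in mock cells and 156 ± 20.8, 595 ± 24.7 and 935 ± 111 with PAMP RNA. The KO response was 0.14 at 1 h (adjusted p = 0.897), 0.41 at 3 h (adjusted p = 0.0109) and 0.37 at 6 h (adjusted p = 0.0147). The calls at 3 and 6 h were lost under quantile normalization (0.29, adjusted p = 0.0816, and 0.06, adjusted p = 0.72). Under scaling to equal total reads, chosen after seeing the data, the values were 0.16 (adjusted p = 0.32) and -0.11 (adjusted p = 0.461). Single libraries also decided them: the value was 0.45 at 1 h without KO mock replicate 2 (adjusted p = 0.0352), 0.29 at 3 h without KO mock replicate 2 (adjusted p = 0.112), and at 6 h 0.33, 0.31 and 0.28 without KO PAMP replicate 2, KO PAMP replicate 3 and KO mock replicate 3 (adjusted p = 0.0557, 0.0713 and 0.0997). The difference between the responses was 0.07 at 1 h, -3.07 at 3 h (SE 0.19, adjusted p = 5.94e-16) and -2.93 at 6 h (SE 0.19, adjusted p = 3.82e-15). In mock cells Dhx58 was higher in KO than in WT cells by 1.19 (SE 0.08, adjusted p = 8.35e-17). This goes against the KO label, while the smaller response of Dhx58 in KO cells goes with it. A count over the whole gene does not show which exons the reads cover. An antisense transcript, Dhx58os, overlaps the gene on chromosome 11 from 100687417 to 100697520, and libraries that do not mark the strand cannot separate the pair. Throughout, WT and KO stand for the libraries labelled so.

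**Figure D1:**
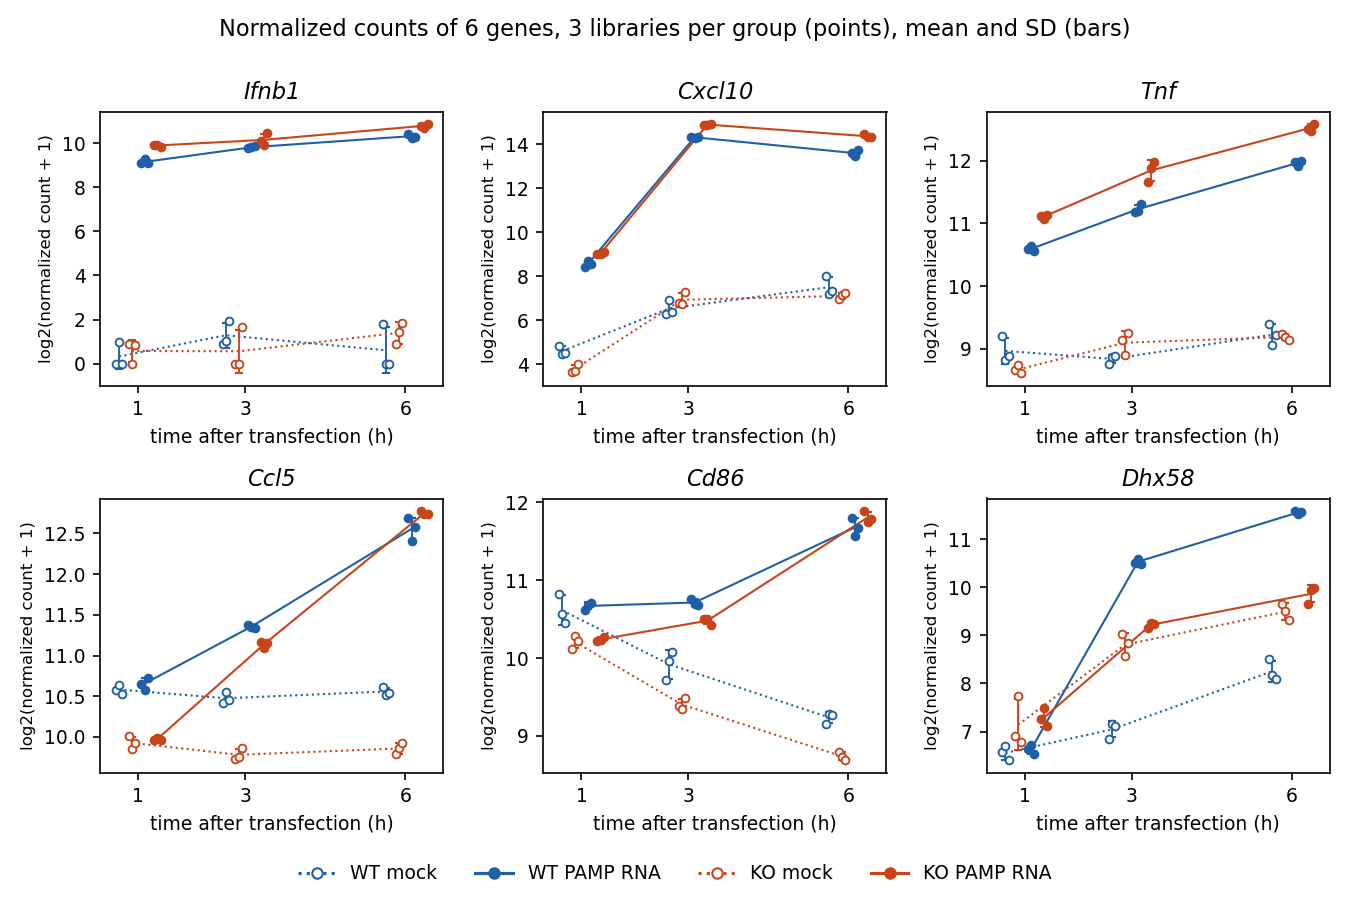
Normalized counts on the log2 scale (count plus 1) of Ifnb1, Cxcl10, Tnf, Ccl5, Cd86 and Dhx58 against hours after transfection, in WT and KO cells, mock and with PAMP RNA; points are the 3 libraries of a group, lines join group means and bars are SD. Dhx58 reached 3005 in WT and 935 in KO cells at 6 h with PAMP RNA, against 307 and 722 in mock cells, while Tnf reached 4001 in WT and 5889 in KO cells.

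The WT responses show which genes changed with PAMP RNA in the libraries labelled WT. After 1 h type I interferon genes and a small set of cytokine and immediate-early genes led. Ifnb1 (interferon beta, chromosome 4, 88522025 to 88522774) had 1 read in the 3 mock libraries and 2019 reads in the 3 PAMP libraries. That is a 1780-fold ratio of normalized counts, with a 95% counting interval of 329 to 72500. Ifna4, an interferon alpha gene (chromosome 4, 88841861 to 88842421), had no read in mock cells and a normalized count of 84.3 ± 10.4 (SD, n = 3) with PAMP RNA, at least 90.3-fold higher. Ifna2, Ifna5 and Ifna1 were at least 28.9-fold, 27.4-fold and 14.8-fold higher. Cxcl10, a chemokine for activated T cells (chromosome 5, 92346638 to 92348889), rose by 3.96 (SE 0.14, adjusted p = 1.64e-26), from 23.5 ± 3.69 to 379 ± 39.3 normalized counts.

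Among 112 genes called at 1 h in WT cells, 95 rose and 17 fell. Of 11 interferon genes tested, 5 rose (6 adjusted over the list alone), with a fitted median of 1.07 (adjusted p = 3.69e-09 with an estimated correlation) and a median of 0.28 with genes without a mock read at their bound. Of 24 inflammatory cytokine genes 6 rose (8 adjusted over the list alone), with a median of 0.31. They included Il6 (3.11, SE 0.29) and Tnf (1.63, SE 0.08, adjusted p = 8.12e-22), both cytokines of acute inflammation. Of 19 chemokine genes 7 rose (7 rose and 2 fell adjusted over the list alone), among them Ccl4 (2.48, SE 0.10) and Cxcl2 (1.83, SE 0.11), which attract monocytes and neutrophils. Of 30 immediate-early genes 12 rose (16 rose and 1 fell adjusted over the list alone), with a median of 0.28. Egr1 (1.90, SE 0.09) and Fos (1.1, SE 0.10) encode transcription factors and Ppp1r15a (1.72, SE 0.08) a regulator of translation under stress. Phlda1 rose by 1.75 (SE 0.09). Of 30 NF-kB targets 4 rose (6 adjusted over the list alone), with a median of 0.04 (adjusted p = 0.028 with an estimated correlation). They included the feedback inhibitors Nfkbiz (1.46, SE 0.10), Tnfaip3 (0.41, SE 0.06) and Nfkbia (0.35, SE 0.06).

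Of 57 interferon-stimulated genes 9 rose and 1 fell at 1 h in WT cells (10 rose and 2 fell adjusted over the list alone), with a median of 0.04. The list's call was lost with an estimated correlation (adjusted p = 0.165 with an estimated correlation). Ifit1 rose by 3.67 (SE 0.16, adjusted p = 2.63e-23), Ifit3 by 2.78 (SE 0.16), Rsad2 by 1.89 (SE 0.14), Isg15 by 1.51 and Oasl1 by 1.42, all effectors against viruses. Ifih1, which encodes MDA5, rose by 0.41 (adjusted p = 0.00175; 0.33 and adjusted p = 0.0618 without WT mock replicate 2). Values that did not pass were 0.27 for Mx1, 0.32 for Irf7, 0.33 for Tlr3, 0.06 for Ddx58 (which encodes RIG-I) and -0.07 for Mavs (its adaptor). The same held for Il1b (0.28), Cd40 (0.21), Ccl5 (0.07), Cd86 (0.06) and Il12b (0.67, adjusted p = 0.0642). Il12b passed under edgeR (adjusted p = 0.0255), and Mx1 did so without WT mock replicate 1 (0.36, adjusted p = 0.0161). Igf1, a growth factor, fell by 0.35 (SE 0.05, adjusted p = 2.27e-05). The scavenger receptor Marco fell by 0.60 (adjusted p = 0.0136), a call lost without WT PAMP replicate 2 (-0.46, adjusted p = 0.313) or WT mock replicate 1 (-0.52, adjusted p = 0.0945). Reads of interferon alpha, Ifit, Gbp, Oas1, Tgtp and H2 genes can be shared within each family, so a value can include reads of a relative.

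After 3 h the interferon-stimulated genes had risen together in WT cells: all 57 tested rose (57 adjusted over the list alone), with a median of 3.48 (adjusted p = 0.000118 with an estimated correlation). Cxcl10 reached 20510 ± 457 normalized counts (SD, n = 3) against 94.1 ± 24.9 in mock cells, a rise of 7.78 (SE 0.14, adjusted p = 1.03e-39). Rsad2, an enzyme that blocks viral replication, rose by 7.59 (SE 0.14), Ifit1 by 7.54 (SE 0.16), Ifit3 by 7.44, Oasl1 by 6.60 and Isg15 by 5.74. Of the RNA sensors, Ifih1 rose by 4.11 (SE 0.08), Tlr3 by 4.05 and Ddx58 by 3.57 (SE 0.09). Irf7, the transcription factor that amplifies interferon alpha, rose by 6.19 (SE 0.18, adjusted p = 2.49e-32). Ifnb1 stood 571-fold and Ifna4 616-fold (interval 146 to 32300) above mock cells.

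At 3 h in WT cells 4925 genes were called, 2322 up and 2603 down. Of 11 interferon genes 9 rose (9 adjusted over the list alone), with a fitted median of 3.14 and 3.56 with bounds. Of 26 genes for guanylate-binding proteins, immunity-related GTPases and IRF1 targets 25 rose (25 adjusted over the list alone), with a median of 4.04, among them Iigp1 (8.24, SE 0.34), Tgtp1 (8.26, from a mock mean of 0.963 normalized counts to 547) and Cxcl9 (7.60, SE 0.34). Among 24 inflammatory cytokine genes, 18 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 1.1. Tnf rose by 2.39, Il6 by 4.97, Il1b by 1.03 and Il12b by 0.71 (adjusted p = 0.00132). Of 19 chemokine genes 15 rose and 1 fell (15 and 2 adjusted over the list alone), with a median of 1.75, and Ccl5 rose by 0.88. NF-kB targets rose with 24 of 30 (25 adjusted over the list alone) and 1 fell, median 0.56; Tnfaip3 rose by 0.65 and Nfkbia by 0.56. Of 25 genes for MHC class I processing 22 rose (22 rose and 1 fell adjusted over the list alone), with a median of 0.86, including the peptide transporter Tap1 (2.10, SE 0.06) and Nlrc5, a transactivator of MHC class I genes (2.19, SE 0.10). Of 20 genes for dendritic cell maturation 14 rose (14 adjusted over the list alone), median 0.39, with the costimulatory receptors Cd40 (3.84, SE 0.14) and Cd86 (0.79).

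Of 30 cell death genes 22 rose at 3 h in WT cells (23 adjusted over the list alone), median 0.58, led by the death ligand Tnfsf10 (5.84) and the nucleic-acid sensor Zbp1 (3.48). Of 40 genes of the RNA-sensing pathway 18 rose and 4 fell (18 and 4 adjusted over the list alone), median 0.11. Mavs fell by 0.49. Mx1 rose by 3.62 and Socs1, a brake on cytokine signalling, by 5.05. Of 30 immediate-early genes 20 rose and 4 fell (20 and 5 adjusted over the list alone), with adjusted p = 0.0901 with an estimated correlation. Of 34 cell cycle genes 3 rose and 14 fell (3 and 14 adjusted over the list alone), median -0.13 (adjusted p = 0.227 with an estimated correlation; 0.0567 at the preset correlation without WT PAMP replicate 2). Cenpf, a kinetochore protein, fell by 0.87. Of 14 MHC class II genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), median 0.07 (adjusted p = 0.959 with an estimated correlation). Among the 10 largest falls were those of Egln3, a prolyl hydroxylase, which fell by 4.76 (SE 0.19, adjusted p = 1.58e-26), Zfp395 by 3.15, Ankrd37 by 3.06, Ddit4 by 2.88 and Bnip3 by 2.33. Egln3 stood at 1388 ± 360 in mock cells at 3 h against 58.0 ± 4.42 at 1 h, and at 49.1 ± 5.84 with PAMP RNA.

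After 6 h WT cells still held high interferon-stimulated genes and had added maturation genes: all 20 tested for dendritic cell maturation rose (20 adjusted over the list alone), median 1.17 (adjusted p = 0.00421 with an estimated correlation). Cd86 rose by 2.44 (SE 0.07, adjusted p = 2.79e-32), from 603 ± 29.5 to 3287 ± 266 normalized counts (SD, n = 3). Cd40 rose by 4.21 (SE 0.14, adjusted p = 3.99e-29), Il12b, a subunit of the T cell-polarising cytokine interleukin-12, by 2.14, the costimulatory ligand Cd70 by 2.59 and the actin bundler Fscn1 by 2.20. Ccl5, a T cell chemokine, rose by 2.00 (SE 0.05), to 6042 ± 570 from 1508 ± 48.5. Cxcl10 rose by 6.09 (SE 0.14, adjusted p = 3.39e-36), to 12470 ± 1260 from 188 ± 61.1.

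At 6 h in WT cells 7754 genes were called, 3803 up and 3951 down. All 57 interferon-stimulated genes rose (57 adjusted over the list alone), median 3.5, with Rsad2 at 6.67, Ifit3 at 6.44, Ifit1 at 6.11, Oasl1 at 5.92, Isg15 at 5.83, Irf7 at 5.65, Ifih1 at 3.75, Mx1 at 3.46, Ddx58 at 3.09 and Tlr3 at 4.05. All 11 interferon genes rose (11 adjusted over the list alone), with a fitted median of 6.95 and 7.98 with bounds; Ifnb1 stood 1530-fold (interval 496 to 7040) and Ifna4 1660-fold (282 to 62100) above mock cells. All 26 genes of the guanylate-binding protein list rose (26 adjusted over the list alone), median 3.94, with Iigp1 at 7.57, Tgtp1 at 7.56 and Cxcl9 at 7.16. Ms4a4c rose by 7.21. Of 24 inflammatory cytokine genes 21 rose and 1 fell (21 and 1 adjusted over the list alone), median 1.85, with Il6 at 3.89, Tnf at 2.74 and Il1b at 1.61. Of 19 chemokine genes 17 rose and 1 fell (17 and 1 adjusted over the list alone), median 1.66. Of 30 NF-kB targets 27 rose and 1 fell (27 and 1 adjusted over the list alone), median 0.72, with Tnfaip3 at 0.95 and Nfkbia at 0.73. Of 25 MHC class I processing genes 23 rose and 1 fell (23 and 1 adjusted over the list alone), median 1.27, with Nlrc5 at 3.14, the class I-like gene H2-T24 at 3.08 and Tap1 at 2.48. Of 30 cell death genes 23 rose and 1 fell (26 and 1 adjusted over the list alone), median 1.06, with Tnfsf10 at 5.29 and Zbp1 at 4.34.

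Of 34 cell cycle genes 5 rose and 22 fell at 6 h in WT cells (5 and 22 adjusted over the list alone), median -0.54 (adjusted p = 0.0115 with an estimated correlation). Cenpf fell by 2.07 (SE 0.08, adjusted p = 1.14e-26) and Cdc20, an activator of mitotic exit, by 1.53. Of 40 RNA-sensing genes 21 rose and 8 fell (23 and 8 adjusted over the list alone), median 0.24, and Mavs fell by 0.74. Of 30 immediate-early genes 23 rose and 3 fell (23 and 3 adjusted over the list alone), median 1.00. Of 14 MHC class II genes 8 rose and 2 fell (8 and 2 adjusted over the list alone), median 0.15 with camera adjusted p = 0.382, and under quantile normalization the median was -0.31 (adjusted p = 0.0201). Of 23 cholesterol synthesis genes 9 rose and 9 fell (9 and 9 adjusted over the list alone), median -0.08 with camera adjusted p = 0.483. The largest falls were Selenbp1 (-3.61), Egln3 (-3.51), Tcp11l2 (-3.23), the ubiquitin ligase gene Rnf150 (-3.17) and the fatty acid desaturase gene Scd2 (-2.54, SE 0.08, adjusted p = 1.97e-31). The share of called genes that rose depended on scaling: at 3 h it was 47.1% as deposited, 33.9% under quantile normalization and 23.0% under scaling to equal total reads, which moved the median gene by -0.18. At 6 h the shares were 49.0%, 40% and 20.8%, and that median shift was -0.37.

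The KO responses answer the same question in the libraries labelled KO. Their Dhx58 reads in mock cells go against that label and their small Dhx58 response goes with it. In KO cells too the interferon, cytokine and immediate-early genes led at 1 h. Ifnb1 went from 2 to 3351 reads (1760-fold, interval 478 to 14300), and Ifna4 was at least 211-fold higher, at 175 ± 9.22 normalized counts (SD, n = 3). Cxcl10 rose by 5.26 (SE 0.14, adjusted p = 7.31e-32), from 13.0 ± 2.01 to 530 ± 22.4. Tnf rose by 2.44 (SE 0.08, adjusted p = 5.8e-29), from 406 ± 17.4 to 2204 ± 54.8, and Egr1 by 2.90 (SE 0.09, adjusted p = 5.8e-29).

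Of 161 genes called at 1 h in KO cells 141 rose and 20 fell, and 83 of those that rose also rose in WT cells (1.1 by chance). Of 11 interferon genes 7 rose (8 adjusted over the list alone), with a median of 2.45 fitted and 2.46 with bounds. Ifna2, Ifna5 and Ifna1 were at least 60.2-fold, 62.2-fold and 36.1-fold higher. Of 57 interferon-stimulated genes 9 rose (14 adjusted over the list alone), median 0.05 (adjusted p = 0.128 with an estimated correlation). They included Ifit1 (4.61), Rsad2 (2.87), Ifit3 (2.81), Isg15 (2.27) and Oasl1 (2.08), and Ifih1 rose by 0.53. Among 24 inflammatory cytokine genes, 9 rose (11 adjusted over the list alone), median 0.29, with Il6 at 4.51 and Il12b at 1.59 (SE 0.18). Of 19 chemokine genes 6 rose (9 rose and 2 fell adjusted over the list alone), median 0.67, with Ccl4 at 3.07 and Cxcl2 at 2.89. Of 30 immediate-early genes 15 rose (17 adjusted over the list alone), median 0.36, with Ppp1r15a at 2.59, Phlda1 at 2.22 and Fos at 1.64. Of 30 NF-kB targets 6 rose (9 adjusted over the list alone), median 0.10, with Nfkbiz at 2.28, Tnfaip3 at 0.98 and Nfkbia at 0.87. Values that did not pass were 0.63 for Irf7 (adjusted p = 0.059; 0.048 under scaling to equal total reads), 0.24 for Il1b, 0.24 for Cd40, 0.19 for Mx1, -0.16 for Tlr3, 0.10 for Ddx58, 0.06 for Mavs, 0.05 for Ccl5 and 0.03 for Cd86. Marco fell by 0.80 (adjusted p = 0.00013). Igf1 fell by 0.26 (adjusted p = 0.0019), a call lost without KO PAMP replicate 2 (-0.21, adjusted p = 0.073) or KO mock replicate 3 (-0.22, adjusted p = 0.0582).

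At 3 h in KO cells 6000 genes were called, 2817 up and 3183 down. Of these, 2138 rose and 2199 fell in both genotypes (551.8 and 699 by chance). All 57 interferon-stimulated genes rose (57 adjusted over the list alone), median 3.76, with Rsad2 at 8.00 (SE 0.14), Cxcl10 at 7.96 (SE 0.14, adjusted p = 1.24e-40), Ifit3 at 7.42, Ifit1 at 7.28, Oasl1 at 6.92, Irf7 at 5.80, Isg15 at 5.73, Ifih1 at 4.49, Tlr3 at 4.29, Mx1 at 4.26 and Ddx58 at 3.58. Of 11 interferon genes 9 rose (9 adjusted over the list alone), with a median of 4.08 fitted and 4.30 with bounds; Ifnb1 stood 1570-fold (interval 489 to 6940) and Ifna4 at least 372-fold above mock cells. All 26 genes of the guanylate-binding protein list rose (26 adjusted over the list alone), median 4.16, with Iigp1 at 8.42, Tgtp1 at 8.41 and Cxcl9 at 8.03. Of 24 inflammatory cytokine genes 20 rose and 1 fell (20 and 1 adjusted over the list alone), median 1.60, with Il6 at 5.06, Tnf at 2.75, Il12b at 1.74 and Il1b at 0.86. Of 25 MHC class I processing genes 22 rose (22 rose and 1 fell adjusted over the list alone), median 0.95, with Nlrc5 at 2.75 and Tap1 at 2.45. Of 20 maturation genes 14 rose (14 adjusted over the list alone), median 0.39, with Cd40 at 4.76 and Cd86 at 1.08. Ccl5 rose by 1.36, Tnfsf10 by 6.25, Zbp1 by 3.86, Tnfaip3 by 0.92 and Nfkbia by 0.65. Mavs fell by 0.61. Egln3 fell by 5.57 (SE 0.19), Ankrd37 by 3.86, Zfp395 by 3.53, Ddit4 by 3.22 and Bnip3 by 2.71. Of 34 cell cycle genes 2 rose and 18 fell (2 and 18 adjusted over the list alone), median -0.16 (adjusted p = 0.134 with an estimated correlation).

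At 6 h in KO cells 8494 genes were called, 4162 up and 4332 down, and 3495 rose and 3512 fell in both genotypes (1335.4 and 1444 by chance). All 57 interferon-stimulated genes rose (57 adjusted over the list alone), median 4.26, with Rsad2 at 7.57, Cxcl10 at 7.26 (SE 0.14), Ifit3 at 7.03, Ifit1 at 6.86, Oasl1 at 6.82, Isg15 at 6.53, Irf7 at 6.52, Tlr3 at 4.82, Ifih1 at 4.42, Mx1 at 4.40 and Ddx58 at 3.42. All 11 interferon genes that passed the filter rose (11 adjusted over the list alone), with a median of 8.23 fitted and 8.93 with bounds. As in WT cells, this count and median were partly set by the filter. Ifnb1 stood 1020-fold and Ifna4 1280-fold (interval 355 to 10600) above mock cells. All 26 genes of the guanylate-binding protein list rose (26 adjusted over the list alone), median 4.52, and all 20 maturation genes rose (20 adjusted over the list alone), median 1.36. Cd40 rose by 4.98 (SE 0.14), Cd86 by 3.07 (SE 0.07), Cd70 by 3.14, Il6 by 4.78, Tnf by 3.34, Ccl5 by 2.89, Il12b by 2.60 and Il1b by 1.58. Tnfaip3 rose by 1.22 and Nfkbia by 0.89. Of 25 MHC class I processing genes 24 rose and 1 fell (24 and 1 adjusted over the list alone), median 1.66, with Nlrc5 at 3.72, H2-T24 at 3.71 and Tap1 at 2.93. Of 34 cell cycle genes 5 rose and 25 fell (5 and 25 adjusted over the list alone), median -0.69 (adjusted p = 0.0138 with an estimated correlation), with Cenpf at -2.52 and Cdc20 at -1.85. Of 23 cholesterol synthesis genes 5 rose and 14 fell (5 and 14 adjusted over the list alone), median -0.26 (adjusted p = 0.273 with an estimated correlation), and Sqle, which encodes squalene epoxidase, fell by 1.17. Mavs fell by 0.79, Egln3 by 5.59 (SE 0.19), Selenbp1 by 4.05, Tcp11l2 by 3.98, Rnf150 by 3.91 and Scd2 by 3.42 (SE 0.08, adjusted p = 7.76e-37). The share of called genes that rose was 47.0% at 3 h as deposited, 34.8% under quantile normalization and 20.8% under scaling to equal total reads. At 6 h it was 49.0%, 40.4% and 20.2%, and the equal-total scaling moved the median gene by -0.25 at 3 h and -0.48 at 6 h.

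**Figure D2:**
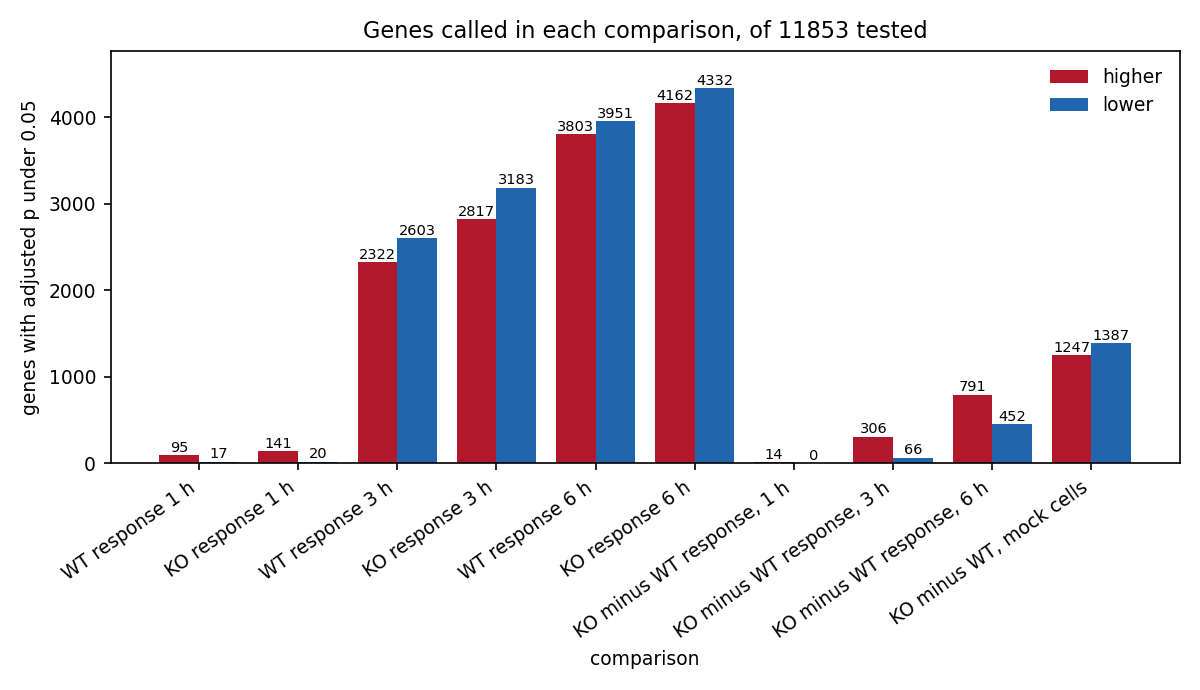
Number of genes past adjusted p of 0.05 in limma for each comparison, with red bars for genes higher and blue bars for genes lower, each with its count. WT cells gave 112, 4925 and 7754 genes at 1, 3 and 6 h and KO cells 161, 6000 and 8494, and the responses differed between genotypes in 14, 372 and 1243 genes.

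The main question of the design is whether the response to PAMP RNA differs between WT and KO cells, tested as the KO response minus the WT response. A direction given for KO cells is one for libraries whose Dhx58 in mock cells goes against the label, while their Dhx58 response goes with it. At 1 h single cytokine and immediate-early genes rose more in KO cells, 1 of 24 and 2 of 30, and the calls of both lists were lost with an estimated correlation (adjusted p = 0.226 and 0.0573). Cxcl10 rose by 5.26 in KO against 3.96 in WT cells, a difference of 1.30 (SE 0.20, adjusted p = 8.4e-05). Egr1 differed by 0.99 (SE 0.13, adjusted p = 7.16e-06), the stress regulator Ppp1r15a by 0.87 (SE 0.11, adjusted p = 7.16e-06), Tnf (chromosome 17, 35199381 to 35202007) by 0.81 (SE 0.11, adjusted p = 9.2e-06) and Cxcl2 by 1.06 (SE 0.16, adjusted p = 8.37e-05).

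In all, limma called 14 genes at 1 h, with 14 that rose more and 0 that fell more in KO cells (550 genes at an unadjusted p under 0.05; 9 called by edgeR and 15 by DESeq2). All 14 were among the 83 genes that rose in both genotypes. The others were Rsad2 (0.98), Ifit2 (0.88), Nfkbiz (0.82), Sdc4 (0.75), Tnfaip3 (0.56), Irg1, which makes itaconate (0.56), Gbp5 (0.53), Nfkbia (0.52) and Zfp36, which destabilises cytokine mRNA (0.42). The 11 interferon genes had a median difference of 0.93 (adjusted p = 0.0174 with an estimated correlation) and of 1.18 with bounds, while limma, edgeR and DESeq2 each called 0 of them (0 adjusted over the list alone; 5 at an unadjusted p under 0.05). Of 30 immediate-early genes 2 rose more (7 adjusted over the list alone), median 0.16 (adjusted p = 0.0573 with an estimated correlation). Of 19 chemokine genes 2 rose more (4 adjusted over the list alone), median 0.19, and of 30 NF-kB targets 3 (4 adjusted over the list alone), median 0.07. For chemokines and for NF-kB targets adjusted p = 0.0776 with an estimated correlation. Among 24 inflammatory cytokine genes, 1 rose more (5 adjusted over the list alone), median 0.04 (adjusted p = 0.226 with an estimated correlation; 0.0508 at the preset correlation without WT mock replicate 1). Values that did not pass were 0.94 for Ifit1 (adjusted p = 0.094; 1.07 and 0.0284 without WT mock replicate 3), 1.40 for Il6 (adjusted p = 0.452; 1.80 and 0.0438 without KO mock replicate 3), 1.05 for Ifna4 (adjusted p = 0.826; 0.99 and 0.00191 with a pseudocount of 8) and 0.50 for Ifnb1. Under edgeR the calls of Cxcl10, Rsad2, Sdc4 (adjusted p = 0.464 each), Ifit2 (0.555) and Gbp5 (0.232; 0.0537 under equal-total scaling) were lost. Leaving out single libraries ended those of Rsad2 (WT PAMP replicate 1, 0.90; WT mock replicate 3, 0.84), Sdc4 (KO mock replicate 2, 0.63), Ifit2 (5 of the 12 libraries, 0.80 to 0.85) and Gbp5 (8 of 12, 0.45 to 0.53), with adjusted p from 0.0556 to 0.201.

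At 3 h some genes of the guanylate-binding protein list, 11 of 26, and of MHC class I processing, 6 of 25, rose more in KO cells, and 0 of 14 MHC class II genes did. Serpina3g, a serine protease inhibitor induced by interferon (chromosome 12, 104236245 to 104241939), differed by 1.19 (SE 0.11, adjusted p = 5.73e-11) and Gbp4, a GTPase of cell-autonomous immunity, by 1.13 (SE 0.15, adjusted p = 2.29e-06). Gbp5, a relative that promotes inflammasome assembly, differed by 0.91 (SE 0.12, adjusted p = 7.22e-07) and Socs1 by 1.08 (SE 0.20, adjusted p = 3e-04). Ccl5 (chromosome 11, 83525778 to 83530518) differed by 0.48 (SE 0.08, adjusted p = 4.55e-05): it went from 1424 ± 68.8 to 2619 ± 32.2 normalized counts (SD, n = 3) in WT cells and from 880 ± 42.3 to 2256 ± 60.1 in KO cells, so the larger KO response ended at a lower count.

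At 3 h the responses of 372 genes differed, 306 upward and 66 downward in KO cells. Of the 2138 genes that rose in both genotypes, 276 rose more in KO cells and 2 less; of the 2199 that fell in both, 47 fell more. Of 26 genes of the guanylate-binding protein list 11 rose more (13 adjusted over the list alone), median 0.43 (adjusted p = 0.00231 with an estimated correlation). Of 25 MHC class I processing genes 6 rose more (10 adjusted over the list alone), median 0.18 (adjusted p = 0.00231 with an estimated correlation). Of 30 NF-kB targets 5 rose more (9 adjusted over the list alone), median 0.15 (adjusted p = 0.0415 with an estimated correlation). Interferon genes had a median of 0.95 (adjusted p = 0.0415 with an estimated correlation) and 0.87 with bounds, with 0 of 11 called by limma, edgeR or DESeq2 (4 adjusted over the list alone; 6 at an unadjusted p under 0.05). Of 57 interferon-stimulated genes 5 rose more (11 adjusted over the list alone), median 0.20 (adjusted p = 0.394 with an estimated correlation), Mx1 among them (0.64, SE 0.11, adjusted p = 0.00022; 0.34 and 0.191 under quantile normalization). Of 24 inflammatory cytokine genes 5 rose more (7 adjusted over the list alone), median 0.36 (adjusted p = 0.0558 with an estimated correlation), and Cd40 differed by 0.92 (adjusted p = 0.00481). Il12b differed by 1.03 (adjusted p = 0.0156), ending at 117 ± 4.14 in WT and 127 ± 12.8 in KO cells from 71.8 ± 12.1 and 38.0 ± 9.02. Il12rb1, a subunit of its receptor, differed by 1.47 and Nlrc5 by 0.55. Downward were Susd3 (-0.85, adjusted p = 0.000561) and Kat2a (-0.60), the acetyltransferase gene next to Dhx58 (chromosome 11, 100704746 to 100712465). Not past the test were Tnf (0.36, adjusted p = 0.0593; 0.0364 under edgeR), Rsad2 (0.42), Cxcl10 (0.18), Ifna4 (0.97; 0.68 and adjusted p = 0.0229 with a pseudocount of 8) and Ifnb1 (1.07, adjusted p = 0.297; 1.63 and 0.034 without KO mock replicate 3).

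The count at 3 h rested on single libraries, at 237 without WT mock replicate 2 and 240 without WT PAMP replicate 1. Quantile normalization gave 242 genes, with 64.0% upward in place of 82.3%, and equal-total scaling, which moved the median gene by -0.07, gave 48.5%. Under quantile normalization the call of Nlrc5 (0.45, adjusted p = 0.103) was lost, as it was under equal-total scaling (adjusted p = 0.0696). Leaving out single libraries ended the calls of Il12b (KO mock replicate 2, 0.85; WT mock replicate 3, 0.91), Nlrc5 (KO mock replicate 2, 0.49; WT PAMP replicate 1, 0.52; WT mock replicate 1, 0.51) and Il12rb1 (5 of 12 libraries, 1.24 to 1.40), with adjusted p from 0.0516 to 0.0735.

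At 6 h interferon-stimulated genes rose more in KO cells: 40 of 57 differed upward (53 adjusted over the list alone), with a median of 0.51 (adjusted p = 0.0276 with an estimated correlation). Cxcl10 ended at 12470 ± 1260 normalized counts (SD, n = 3) in WT and 21180 ± 1080 in KO cells, from 188 ± 61.1 and 138 ± 12.4, a difference in response of 1.17 (SE 0.20, adjusted p = 4.11e-05). Tnf ended at 4001 ± 122 and 5889 ± 228, from 600 ± 69.5 and 582 ± 20.1, a difference of 0.59 (SE 0.11, adjusted p = 0.000153). Mx1, a GTPase that blocks influenza virus (chromosome 16, 97447035 to 97462907), differed by 0.94 (SE 0.11, adjusted p = 6.94e-08) and Ifih1 by 0.67 (SE 0.12, adjusted p = 6.84e-05). Serpina3g differed by 1.35 (SE 0.11, adjusted p = 7.29e-13) and Gbp4 by 1.15 (SE 0.15, adjusted p = 5.9e-07).

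At 6 h 1243 genes differed in response, 791 upward and 452 downward in KO cells. Of 3495 genes that rose in both genotypes 719 rose more and 8 less in KO cells, and of 3512 that fell in both 324 fell more and 5 less. Between 3 and 6 h, 202 genes were shared among those that differed upward (20.4 by chance) and 24 among those that differed downward (2.5 by chance). Of 26 genes of the guanylate-binding protein list 16 rose more (19 adjusted over the list alone), median 0.62 (adjusted p = 0.00227 with an estimated correlation). Of 25 MHC class I processing genes 16 rose more (21 adjusted over the list alone), median 0.34 (adjusted p = 3.48e-05 with an estimated correlation), with H2-T10 at 0.71 and Nlrc5 at 0.58. Of 30 NF-kB targets 12 rose more (19 adjusted over the list alone), median 0.23 (adjusted p = 0.00893 with an estimated correlation). Among 24 inflammatory cytokine genes, 8 rose more (11 adjusted over the list alone), median 0.47 (adjusted p = 0.0413 with an estimated correlation). Of 30 cell death genes 14 rose more and 1 less (17 and 1 adjusted over the list alone), median 0.26 (adjusted p = 0.00954 with an estimated correlation), with Tnfsf10 at 0.77 and the necroptosis effector Mlkl at 0.64. Of 40 RNA-sensing genes 11 differed upward and 2 downward (16 and 3 adjusted over the list alone), median 0.12 (adjusted p = 0.0413 with an estimated correlation; 0.0676 at the preset correlation under quantile normalization).

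Of 20 maturation genes 10 rose more in KO cells at 6 h (11 adjusted over the list alone), median 0.25 (adjusted p = 0.0413 with an estimated correlation). Cd86 differed by 0.63 (SE 0.10, adjusted p = 1.7e-05) and ended at 3287 ± 266 normalized counts (SD, n = 3) in WT and 3588 ± 184 in KO cells, from 603 ± 29.5 and 426 ± 15.4. Ccl5 differed by 0.89 (SE 0.08, adjusted p = 9.09e-12) and ended at 6042 ± 570 and 6884 ± 109. Cd40 differed by 0.77 (adjusted p = 0.00954; 0.61 and 0.051 under quantile normalization). Ptgs2 (1.47), which makes prostaglandins, Nos2 (1.44), which makes nitric oxide, Ch25h (1.40), which makes an antiviral oxysterol, and Klrk1 (1.23), an activating receptor, were among the largest upward differences. Rsad2 differed by 0.90 (adjusted p = 0.0013), Oasl1 by 0.90, Irf7 by 0.86, Tlr3 by 0.77 and Ifit1 by 0.75. Downward, 8 of 23 cholesterol synthesis genes differed (10 adjusted over the list alone), median -0.16 (adjusted p = 0.0125 with an estimated correlation), with Sqle at -0.76 (SE 0.08), Stard4, a sterol carrier, at -0.71 and Msmo1 at -0.62. Egln3 differed by -2.07, Zfp395 by -2.16, Ddit4 by -1.37, Ankrd37 by -1.28 and Kat2a by -1.24. Mid1, a ubiquitin ligase gene on chromosome X, differed by -2.37: it went from 115 ± 8.28 to 849 ± 31.5 in WT cells and from 16.8 ± 6.10 to 23.4 ± 4.42 in KO cells. Not past the test were Isg15 (0.70, adjusted p = 0.0613; 0.00164 under edgeR), Ifit3 (0.59, adjusted p = 0.0778; 0.00058 under edgeR), Ddx58 (0.33, adjusted p = 0.0952; 0.0225 under edgeR), Il6 (0.90), Il12b (0.46), Ifna4 (0.35; 0.60 and adjusted p = 0.0236 with a pseudocount of 8) and Ifnb1 (-0.32, adjusted p = 0.746). The interferon genes had a median of 0.78 (camera adjusted p = 0.111; 0.93 and 1.57e-08 with a pseudocount of 8) and 0.81 with bounds, with 0 of 11 called by limma, edgeR or DESeq2 (0 adjusted over the list alone; 1 at an unadjusted p under 0.05).

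WT mock replicate 1 at 6 h stood apart, with a mean log2 level of the interferon-stimulated genes of 8.83 against 8.32 and 8.39 in the other mock libraries of its group. Without it 920 genes differed at 6 h, and the calls of Ch25h (0.93), Irf7 (0.59), Ifit1 (0.48), Oasl1 (0.65), Tnfsf10 (0.51) and Ankrd37 (-0.74) were lost, with adjusted p from 0.0518 to 0.145. Leaving out other single libraries ended the calls of Ptgs2 (KO mock replicate 2, 1.31; WT PAMP replicate 2, 1.39; WT mock replicate 3, 1.24), Nos2 (KO PAMP replicate 1, 1.37; WT PAMP replicate 3, 1.19; WT mock replicate 3, 1.13) and Ifit1 (KO PAMP replicate 1, 0.71; KO mock replicate 1, 0.68; WT PAMP replicate 2, 0.68). Quantile normalization ended those of Ptgs2, Ch25h, Irf7, Ifit1, Nlrc5 and Tnfsf10 (adjusted p from 0.0534 to 0.0857), and equal-total scaling that of Ifit1 (0.0532). It gave 42.5% of called genes upward in place of 63.6%, and equal-total scaling, which moved the median gene by -0.11, gave 23.3%. Of the list scores, each the mean of a list's genes in a library, none passed an exact two-sided permutation test adjusted over 42 tests: the interferon-stimulated score rose by 3.75 ± 0.28 in WT and 4.30 ± 0.11 in KO cells (difference 0.55, exact p = 0.01, adjusted 0.07). The smallest exact p was 0.005, with adjusted p = 0.0525, for MHC class I processing at 3 h (0.17) and 6 h (0.33), immediate-early genes at 3 h (0.14) and NF-kB targets at 6 h (0.24). These relabellings mix the genotypes and so carry their difference in mock cells. With the mean genotype difference removed first, a test chosen after seeing the data whose p-values are approximate, 5, 8 and 9 of 14 scores passed at 1, 3 and 6 h. The interferon-stimulated score at 6 h (adjusted p = 0.0124) and the maturation score at 6 h (0.28, adjusted p = 0.0124 against 0.601 before) were among them.

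**Figure D3:**
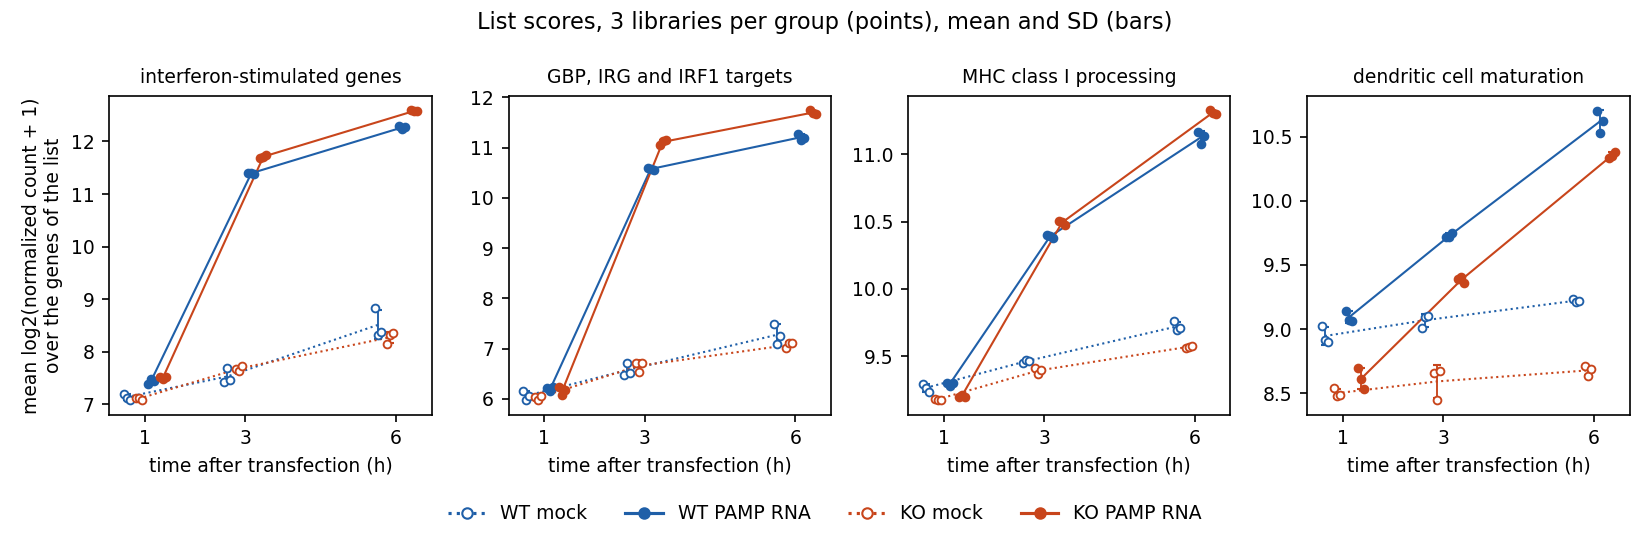
Mean log2 level of the genes of 4 lists (interferon-stimulated, guanylate-binding protein, MHC class I processing and dendritic cell maturation) in each library against hours after transfection; points are libraries, 3 per group, lines join group means and bars are SD. At 6 h the interferon-stimulated score rose by 3.75 in WT and 4.30 in KO cells.

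Tested over all times at once, 1115 genes differed in response between genotypes. Dhx58 (adjusted p = 6.14e-20) and Serpina3g (adjusted p = 5.87e-16) led. Next were Ccnd2, a cyclin of the G1 phase, the matrix proteoglycan gene Vcan, Ccl5 and Fgl2, with adjusted p of 7.71e-13, 1.8e-12, 2.3e-12 and 1.21e-11. Ccnd2 differed by 0.70 at 3 h and 0.75 at 6 h, Vcan by 0.79 and 0.75, and Fgl2 by 0.62 and 0.81. Stimulated KO cells were also compared with stimulated WT cells directly, a comparison chosen after seeing the data, and 1084, 2620 and 2848 genes differed at 1, 3 and 6 h. At 6 h Cxcl10 was 0.77 higher in stimulated KO cells (SE 0.14, adjusted p = 3.58e-05), Tnf 0.56, Rsad2 0.67, Ch25h 1.55 and Nos2 0.98. Cd86 (0.13, adjusted p = 0.191), Cd40 (0.34, adjusted p = 0.0809), Il12b (-0.02, adjusted p = 0.947) and Ifnb1 (0.47, adjusted p = 0.342) did not pass. At 1 h some of the lists already lower in KO mock cells were lower in stimulated KO cells too. Maturation genes (15 of 20 lower, median -0.57), MHC class II genes (8 of 14, -0.43) and markers of conventional dendritic cells (8 of 14, -0.42) led these (15, 8 and 9 adjusted over the list alone; adjusted p up to 0.000422 with an estimated correlation). Their medians were -0.37, -0.36 and -0.30 at 3 h and -0.39, -0.28 and -0.17 at 6 h (adjusted p up to 0.0422 with an estimated correlation). At 1 h, of 30 immediate-early genes 11 were lower and 1 higher (15 and 1 adjusted over the list alone), median -0.17, and of 30 NF-kB targets 10 and 2 (14 and 2 adjusted over the list alone), median -0.12, with adjusted p = 0.0219 for each with an estimated correlation. Among 19 chemokine genes, 7 were lower and 1 higher (7 and 3 adjusted over the list alone), median 0.02, with adjusted p = 0.0884 with an estimated correlation. In mock cells at 1 h 19 of 30 immediate-early genes were lower in KO cells (22 lower and 1 higher adjusted over the list alone), median -0.43 (adjusted p = 0.00045 with an estimated correlation). Interferon genes were higher with PAMP RNA at 1 h, 5 of 11 (5 adjusted over the list alone), median 0.93 (adjusted p = 0.0163 with an estimated correlation), with Ifna4 at 1.05 (adjusted p = 0.00522). Il6 (1.00, adjusted p = 0.0204), Tnf (0.51, adjusted p = 2.7e-06), Cxcl10 (0.49, adjusted p = 0.0165) and Egr1 (0.35, adjusted p = 0.008) were higher too. Ccl5 (-0.68, adjusted p = 1.47e-13) and Cxcl3 (-0.58, adjusted p = 1.1e-06) were lower, and Cxcl2 did not pass (0.02).

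**Figure D4:**
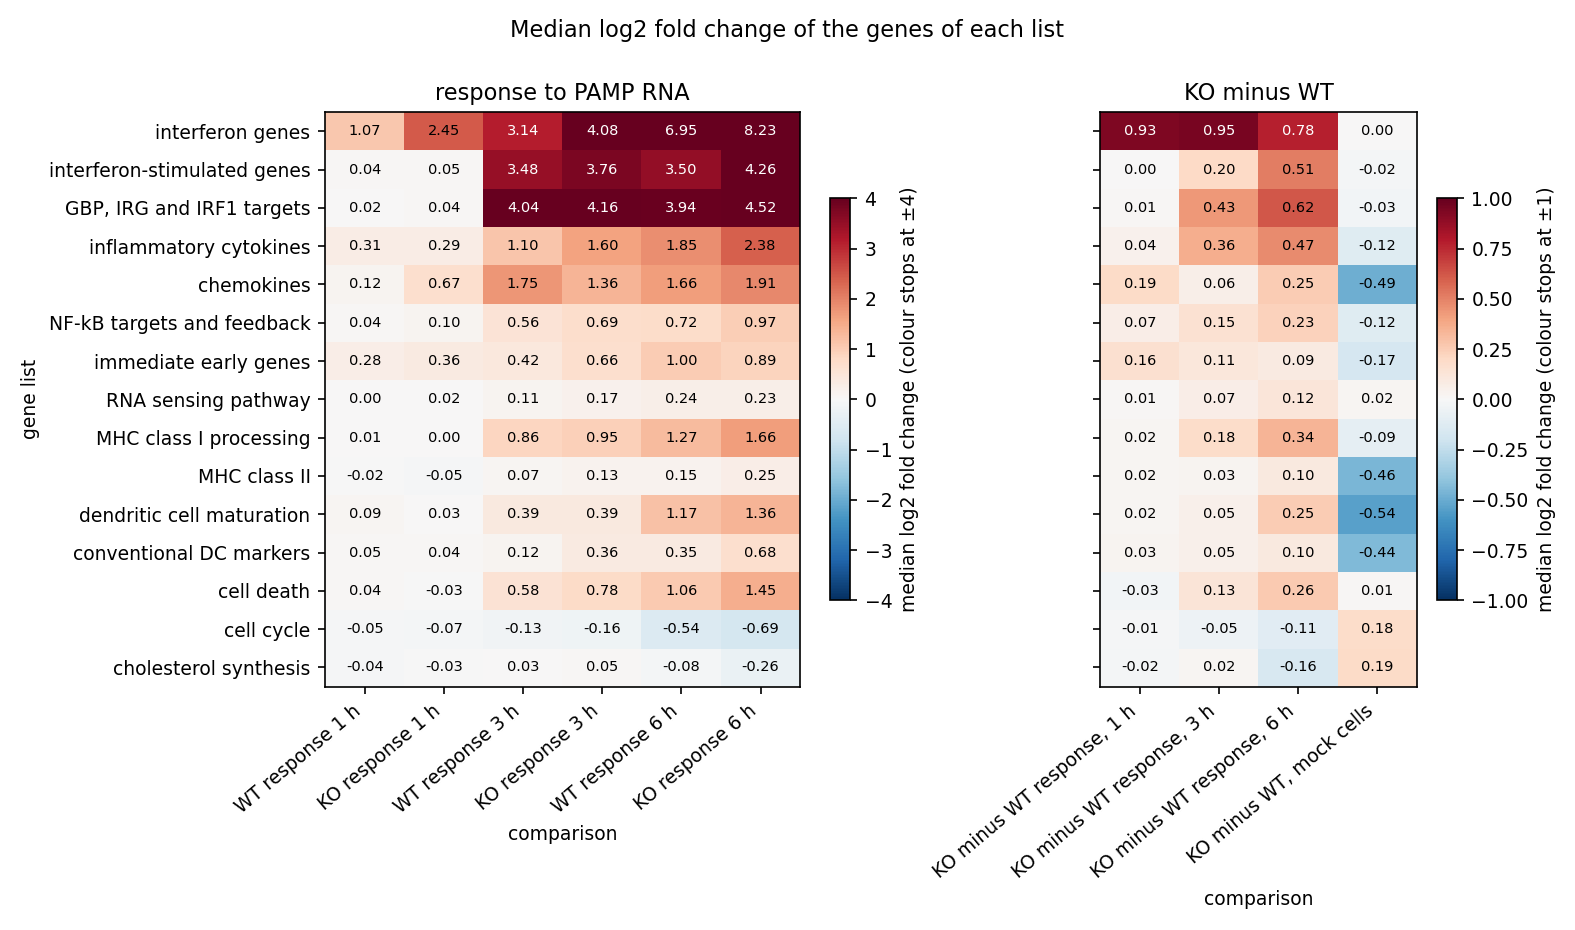
Median log2 change of the tested genes of 15 lists in 10 comparisons, printed in each cell and drawn in red where higher and blue where lower. Interferon-stimulated genes stood at 3.5 in WT and 4.26 in KO cells at 6 h and maturation genes at -0.54 in KO against WT mock cells, while the MHC class II medians at 6 h, 0.15 and 0.25, were -0.31 and -0.35 under quantile normalization.

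The comparison of mock cells shows how the genotypes differed before PAMP RNA. Maturation and antigen-presentation genes were lower in KO mock cells: 16 of 20 maturation genes (16 adjusted over the list alone), median -0.54 (adjusted p = 2.26e-05 with an estimated correlation), and 12 of 14 MHC class II genes (1 higher and 12 lower adjusted over the list alone), median -0.46 (adjusted p = 0.000313 with an estimated correlation). Ccr7, the receptor that guides mature dendritic cells to lymph nodes, was lower (-0.78, SE 0.03, adjusted p = 1.72e-24), as were H2-Eb1 (-0.70, SE 0.02, adjusted p = 1.04e-26) and H2-Ab1 (-0.65, SE 0.03), both chains of MHC class II. Ccl5 was lower (-0.68, SE 0.03, adjusted p = 9.07e-23), at 1508 ± 48.5 normalized counts in WT and 928 ± 43.8 in KO mock cells at 6 h (SD, n = 3). Wdfy1, an endosomal protein, was higher by 1.69 (SE 0.05, adjusted p = 4.24e-31) and Nnt, the mitochondrial transhydrogenase, by 1.04 (SE 0.05, adjusted p = 4.08e-22).

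In mock cells 2634 genes differed, 1247 higher and 1387 lower in KO cells. Of 14 markers of conventional dendritic cells 13 were lower and 1 higher (13 and 1 adjusted over the list alone), median -0.44 (adjusted p = 1.2e-05 with an estimated correlation), Itgae among them (-0.83). Of 17 macrophage markers 6 were higher and 5 lower (6 and 5 adjusted over the list alone), median 0.02 with camera adjusted p = 0.754. Of 6 plasmacytoid markers 4 were lower (4 adjusted over the list alone), median -0.15 (adjusted p = 0.0134 with an estimated correlation). Of 19 chemokine genes 13 were lower and 2 higher (14 and 3 adjusted over the list alone), median -0.49, with Cxcl3 at -0.74 and Ppbp at -0.93. NF-kB targets were lower for 17 of 30 (17 lower and 1 higher adjusted over the list alone), median -0.12, and MHC class I processing genes for 11 of 25 (11 adjusted over the list alone), median -0.09. Of 57 interferon-stimulated genes 7 were higher and 14 lower (7 and 14 adjusted over the list alone), median -0.02 with camera adjusted p = 0.282 (0.0181 without WT mock 6 h replicate 2), and Mx1 was lower (-0.44). Of 34 cell cycle genes 24 were higher (24 adjusted over the list alone), median 0.18 (adjusted p = 0.000948 with an estimated correlation), with Ccna2, a cyclin of S phase, at 0.31. Of 23 cholesterol synthesis genes 18 were higher and 1 lower (19 and 1 adjusted over the list alone), median 0.19 (adjusted p = 0.00326 with an estimated correlation), with Lss at 0.36 and Sqle at 0.28. For inflammatory cytokines 1 was higher and 9 lower of 24 (1 and 9 adjusted over the list alone), with adjusted p = 0.101 with an estimated correlation.

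Of single genes in mock cells, Il12b (-0.79), Cd200 (-0.84), Cd40 (-0.52) and Cd86 (-0.47) were lower in KO cells. The falls also took in Mid1 (-2.54, SE 0.13, adjusted p = 3.39e-21), Pydc3 (-1.44), Apol7c (-1.42) and Ramp3 (-1.06). The aminopeptidase gene Rnpep (0.98), Plxnb2 (0.93), the haemoglobin scavenger receptor gene Cd163 (0.77) and Kat2a (0.53) were higher. Cxcl10 was lower (-0.27), a call lost under edgeR (-0.32, adjusted p = 0.101). Erdr1 had 1097, 674 and 607 reads in WT mock cells at 1, 3 and 6 h and 1, 0 and 0 in KO mock cells. Taken time by time, a comparison chosen after seeing the data, 1377, 974 and 1309 genes differed between the mock cells at 1, 3 and 6 h. The NF-kB medians were then -0.19, 0.01 and -0.14 (adjusted p = 0.000455, 0.493 and 0.0136 with an estimated correlation) and the interferon-stimulated medians -0.03, 0.14 and -0.23 (0.952, 0.478 and 0.184).

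The last comparison asks how responses moved between 3 and 6 h. In both genotypes those of maturation and MHC class I genes grew and some early ones shrank. Cd86 rose further by 1.65 in WT (SE 0.10, adjusted p = 7.22e-18) and 1.99 in KO cells (SE 0.10), and Ccl5 by 1.12 and 1.53 (SE 0.08). The Cxcl10 response fell by 1.69 in WT (SE 0.20, adjusted p = 1.71e-09), where mock counts also rose, and 0.71 in KO cells. Ccl7, a monocyte chemokine, rose further by 2.27 (SE 0.32, adjusted p = 1.2e-07) and 2.38 (SE 0.32). Cenpf fell further by 1.20 and 1.67.

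Between 3 and 6 h, 4064 genes differed in WT cells, 2284 upward and 1780 downward, and 4838 in KO cells, 2697 and 2141. Of 20 maturation genes 16 moved up in WT cells (16 adjusted over the list alone), median 0.61, and 17 in KO cells (17 adjusted over the list alone), median 0.74. Of 25 MHC class I processing genes 17 (18 adjusted over the list alone), median 0.58, and 23 (23 adjusted over the list alone), median 0.67, did so. Of 34 cell cycle genes 22 moved down and 3 up in WT cells (22 and 3 adjusted over the list alone), median -0.40, and 21 and 6 in KO cells (22 and 6 adjusted over the list alone), median -0.45. Of 11 interferon genes 11 moved up in WT cells (11 adjusted over the list alone), fitted median 3.79, and 9 in KO cells (9 adjusted over the list alone), fitted median 3.57. In each genotype edgeR called 0 of these and DESeq2 4, and in KO cells the list did not pass with a filter at a mean of 50 (1.40, adjusted p = 0.131). Interferon-stimulated genes moved both ways, with 16 up and 24 down in WT cells (16 and 24 adjusted over the list alone), median -0.16, camera adjusted p = 0.251 (0.0169 without WT mock 6 h replicate 2 and 0.0325 without WT mock 3 h replicate 2). In KO cells 23 went up and 7 down (23 and 7 adjusted over the list alone), median 0.17, with adjusted p = 0.759 with an estimated correlation and a median of -0.21 under quantile normalization. Ifit1 moved by -1.43 in WT cells (SE 0.22, adjusted p = 1.5e-06). KO cells gave -0.41 (adjusted p = 0.141; -0.97 and 0.0016 under quantile normalization; -0.67 and 0.00947 without KO mock 3 h replicate 3). Isg15 rose further in KO cells by 0.79 (adjusted p = 0.0086), a call lost under quantile normalization (0.21, adjusted p = 0.561) or equal-total scaling (0.56, adjusted p = 0.0644). Il12b rose further by 1.43 in WT and 0.86 in KO cells, and Tcp11l2 fell further by 2.80 and 2.99. The share upward was 56.2% in WT cells as deposited, 46.1% under quantile normalization and 22.7% under equal-total scaling, and in KO cells 55.7%, 46.8% and 23.1%, with median shifts of -0.19 and -0.23.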

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

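Of the tests here, those with the mean genotype difference removed and those on library scaling, culture state, a strain difference elsewhere, read-through from Kat2a, mislabelled libraries and exchanged labels were chosen only after the result was seen. Each value in the next paragraphs is a difference between responses that passed its own test, in log2 units.

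At 1 h 14 genes rose more in KO cells: Cxcl10 (1.30), Cxcl2 (1.06), Egr1 (0.99), Rsad2 (0.98), Ifit2 (0.88), Ppp1r15a (0.87), Nfkbiz (0.82), Tnf (0.81), Sdc4 (0.75), Tnfaip3 (0.56), Irg1 (0.56), Gbp5 (0.53), Nfkbia (0.52) and Zfp36 (0.42). The median of the interferon genes differed by 0.93. At 3 h 372 genes differed, with list medians of 0.95 for interferon genes, 0.43 for the guanylate-binding protein list, 0.15 for NF-kB targets and 0.18 for MHC class I processing. The genes named were Il12rb1 (1.47), Serpina3g (1.19), Gbp4 (1.13), Socs1 (1.08), Il12b (1.03), Cd40 (0.92), Gbp5 (0.91), Vcan (0.79), Ccnd2 (0.70), Mx1 (0.64), Fgl2 (0.62), Nlrc5 (0.55) and Ccl5 (0.48), and downward Dhx58 (-3.07), Susd3 (-0.85) and Kat2a (-0.60).

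At 6 h 1243 genes differed, and 1115 over all times. List medians differed by 0.51 for interferon-stimulated genes, 0.62 for the guanylate-binding protein list, 0.47 for inflammatory cytokines, 0.23 for NF-kB targets, 0.12 for RNA sensing, 0.34 for MHC class I processing, 0.25 for maturation, 0.26 for cell death and -0.16 for cholesterol synthesis. Upward were Ptgs2 (1.47), Nos2 (1.44), Ch25h (1.40), Serpina3g (1.35), Klrk1 (1.23), Cxcl10 (1.17), Gbp4 (1.15), Mx1 (0.94), Rsad2 (0.90), Oasl1 (0.90), Ccl5 (0.89), Irf7 (0.86), Fgl2 (0.81), Tlr3 (0.77), Cd40 (0.77), Tnfsf10 (0.77), Ccnd2 (0.75), Vcan (0.75), Ifit1 (0.75), H2-T10 (0.71), Ifih1 (0.67), Mlkl (0.64), Cd86 (0.63), Tnf (0.59) and Nlrc5 (0.58). Downward were Dhx58 (-2.93), Mid1 (-2.37), Zfp395 (-2.16), Egln3 (-2.07), Ddit4 (-1.37), Ankrd37 (-1.28), Kat2a (-1.24), Sqle (-0.76), Stard4 (-0.71) and Msmo1 (-0.62).

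Between 3 and 6 h the response changed for 4064 genes in WT and 4838 in KO cells. In WT cells the list medians were 3.79 for interferon genes, 0.58 for MHC class I processing, 0.61 for maturation, -0.40 for the cell cycle, 0.39 for unfolded-protein and integrated stress genes and 0.50 for heat shock, and in KO cells 3.57, 0.67, 0.74, -0.45, 0.34 and 0.62. The interferon medians were in part set by the filter on mean counts. The genes named were Ccl5 (1.12), Cd86 (1.65), Il12b (1.43), Cxcl10 (-1.69), Ifit1 (-1.43), Cenpf (-1.20), Tcp11l2 (-2.80) and Ccl7 (2.27) in WT cells, and Ccl5 (1.53), Cd86 (1.99), Il12b (0.86), Cxcl10 (-0.71), Cenpf (-1.67), Tcp11l2 (-2.99), Ccl7 (2.38) and Isg15 (0.79) in KO cells.

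Other splits of the libraries were counted for each comparison, with the real one included. For the responses only 10 splits exist, too few for a share under 0.05. In WT cells 1 of 10 called as many genes as the 112, 4925 and 7754 at 1, 3 and 6 h, and the highest other splits called 2, 0 and 13. In KO cells 1 of 10 called as many as the 161, 6000 and 8494, and the highest other called 1 each. In mock cells 1 of 100 splits called as many as 2634, the highest other 1484, so chance was excluded. For the genotype difference in response 14, 20 and 6 of 100 splits called as many as 14, 372 and 1243 genes at 1, 3 and 6 h, and the highest others called 937, 2054 and 1644. Chance was not excluded at 1, 3 or 6 h. Splits far above the real count at 1 and 3 h point to a structure of the samples. They mix genotypes that differ in mock and stimulated cells alike. Over all times 3 of 100 splits reached 1115 (highest other 1632), so chance was excluded for libraries.

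For 6 against 3 h, 7 of 100 splits reached 4064 in WT cells (highest other 5128) and 7 of 100 reached 4838 in KO cells (highest other 5449), so chance was not excluded. Those splits mix the times, between which mock cells alone differed in 5181 genes in WT and 5132 in KO cells. With the mean difference over both treatments removed first, 1 of 100 splits reached the real count in each case. The highest others were then 6, 44 and 313 at 1, 3 and 6 h, 56 over all times, and 2101 in WT and 2608 in KO cells for 6 against 3 h, so chance was excluded by these splits.

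The first pattern weighed is the larger responses of KO cells at 6 h. A scaling of whole libraries would move genes that rise and genes that fall alike, but the median difference was 0.16 for genes that rose and -0.11 for genes that fell in both genotypes, a gap of 0.27 against at most 0.23 in other splits, which argues against it as the whole cause. A larger share of responding cells in the KO cultures stays open: of 228 strongly induced genes, 1.32% (3 genes) lay below WT in stimulated cells and 113 lay above, with quartiles of 0.30 to 0.67. The state of the cultures cannot be told apart from genotype, because KO mock cells differed in maturation genes before PAMP RNA (median -0.54) and the number of cultures behind a genotype is not given in the sources used here. A loss of LGP2 that lets the response run higher stays possible, untested beside these.

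The second pattern is the difference between mock cells. Another strain's DNA around Dhx58 would gather calls near it. The 2.02% of calls within 10 Mb cannot decide, as only 209 tested genes lay there. Of these 24.4% were called against 22.2% elsewhere (odds ratio 1.13, Fisher's exact two-sided p = 0.451), so calls did not gather. Effects elsewhere or on single neighbours such as Kat2a stay open. A strain difference elsewhere in the genome cannot be told apart from the loss of LGP2, since each genotype comes with its own mice; Nnt, whose level differs between mouse substrains as a known background fact, was 1.04 higher in KO cells and Erdr1 and Mid1 were lower. The loss of LGP2 itself stays open as well, untested.

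The third pattern is the Dhx58 reads in KO cells. Read-through from the neighbour Kat2a would follow its level, but Dhx58 rose by 2.35 in KO mock cells between 1 and 6 h and Kat2a by 0.19, a gap of 2.16, which argues against it. Single mislabelled or swapped libraries are argued against by 0 of 36 libraries that lay nearer to the other genotype. Each was placed by the 50 genes that best separated the genotypes in the other libraries, and 6 of 6 exchanges put in on purpose were found. An exchange of the 2 genotype labels as a whole cannot be told apart from labels that are right: Dhx58 was 1.19 higher in KO mock cells but 1.69 lower in stimulated KO cells at 6 h, which go opposite ways. A targeted allele that still makes part of the transcript, or reads of the antisense Dhx58os, stays open, since a count per gene does not show exons or strand.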

How the results depend on the processing

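Of the alternatives, only scaling to equal total reads was chosen after the results were seen. Of 369 gene results named, 43 changed side of the threshold or direction under at least 1 alternative, and of 172 list results 51. TMM scaling changed none of the 369 gene results. Quantile normalization ended 12 gene calls and added 1, edgeR ended 8 and added 5, a pseudocount of 8 ended 1 and added 7, and equal-total scaling ended 5, added 3 and reversed 1. Leaving out single libraries ended a gene call in 53 of the refits and added one in 16, against 3069 without change. An estimated correlation ended 37 list calls, and of all list tests 96 in place of 159 passed. The replicate block, with 1235 genes for the genotype difference at 6 h, added 3 gene calls and changed no list call among the 172.

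Requiring a 2-fold change gave 43, 875 and 1801 genes in WT cells at 1, 3 and 6 h, 59, 1269 and 2493 in KO cells, 2, 20 and 76 for the genotype difference in response, 27 in mock cells, and 527 in WT and 740 in KO cells for 6 against 3 h. These are fewer by construction. For the genotype difference at 1 h edgeR gave 9 genes in place of 14. At 3 h quantile normalization gave 242 and array weights 729 in place of 372. At 1 h a fit on the libraries compared gave 69 genes in WT cells in place of 112, with fewer libraries to measure the spread, and array weights gave 247 in KO cells in place of 161. For edgeR, quantile normalization and array weights the cause was not tested. Reversed were the MHC class II medians under quantile normalization (WT 6 h -0.31, KO 3 h -0.22, KO 6 h -0.35), the interferon-stimulated median of KO cells between 3 and 6 h (-0.21 under quantile normalization) and Dhx58 in KO cells at 6 h (-0.11 under equal-total scaling); the cause was not tested.

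Without each library in turn the counts ran from 75 to 135, 4318 to 4490 and 7220 to 7517 in WT cells at 1, 3 and 6 h, and from 120 to 158, 5539 to 5740 and 8070 to 8211 in KO cells. The genotype difference in response ran from 12 to 19, 237 to 417 and 920 to 1210, and over all times from 920 to 1241. Mock cells gave 2397 to 2675 genes, 6 against 3 h gave 3603 to 4095 in WT and 4388 to 4675 in KO cells, and 155 to 163 list tests passed. Depth limits the interferon genes, since most had no mock read: 10, 10 and 7 of 11 lacked one in WT or KO mock cells at 1, 3 and 6 h.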

Other observations

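Of the values here, the hypoxia list, its test and the comparisons within mock or stimulated cells were chosen only after the result was seen. The response of heat shock genes moved up between 3 and 6 h in both genotypes, from medians of -0.13 in WT and -0.17 in KO cells at 3 h (camera adjusted p = 0.771 and 0.547). In WT cells 10 of 14 rose and 1 fell (10 and 1 adjusted over the list alone), median 0.50 (adjusted p = 0.00208 with an estimated correlation), with the chaperone genes Dnaja1 (1.03), Dnajb1 (0.97) and Hspa1b (0.85). In KO cells 10 rose and 1 fell (10 and 1 adjusted over the list alone), median 0.62 (adjusted p = 0.00445 with an estimated correlation), with Hspa1b at 1.20 and Dnaja1 at 1.09. Of 22 unfolded-protein and integrated stress genes 17 moved up and 1 down in WT cells (18 and 1 adjusted over the list alone), median 0.39 (adjusted p = 0.0083 with an estimated correlation). In KO cells 14 rose and 2 fell (16 and 2 adjusted over the list alone), median 0.34 (adjusted p = 0.027 with an estimated correlation), from 0.05 and -0.03 at 3 h (camera adjusted p = 0.948 and 0.971). Ddit3, a transcription factor of the integrated stress response, moved up by 0.88 and 1.37, and Hspa5, the main chaperone of the endoplasmic reticulum, by 0.74 and 1.08. Against mock cells at 6 h the heat shock median was 0.46 in WT cells, with adjusted p = 0.0536 with an estimated correlation, and 0.12 under quantile normalization. The median of the unfolded-protein and integrated stress genes was 0.33 in WT and 0.35 in KO cells at 6 h, with adjusted p = 0.122 and adjusted p = 0.219 with an estimated correlation. It was 0.02 and -0.04 under quantile normalization and -0.05 and -0.13 under equal-total scaling.

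Of 18 glycolysis genes 16 fell and 2 rose at 3 h in WT cells (16 and 2 adjusted over the list alone), median -0.40, and 13 fell and 2 rose in KO cells (15 and 2 adjusted over the list alone), median -0.36. Both calls were lost with an estimated correlation (adjusted p = 0.217 and adjusted p = 0.381 with an estimated correlation). At 6 h 13 fell and 3 rose in WT cells (13 and 3 adjusted over the list alone), median -0.50, and 14 fell and 3 rose in KO cells (14 and 3 adjusted over the list alone), median -0.61, with adjusted p = 0.457 and adjusted p = 0.473 with an estimated correlation. Hdc, the enzyme that makes histamine, stood at 1.43 normalized counts in WT mock cells and 101 ± 10.6 (SD, n = 3) with PAMP RNA at 6 h, and at 162 ± 12.7 in stimulated KO cells. In mock cells 8 of 18 genes of the oxidative stress response driven by NRF2 were lower in KO cells (8 adjusted over the list alone), median -0.11 (adjusted p = 0.00704 with an estimated correlation), and 13 of 25 lysosome genes were higher and 2 lower (14 and 3 adjusted over the list alone), median 0.09 (adjusted p = 0.172 with an estimated correlation).

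Genes known to be induced by low oxygen were lower with PAMP RNA at 3 h. Their list was written after the falls of 5 members, Egln3, Ankrd37, Bnip3, Ddit4 and Ero1l, were seen, so a p-value of the list would be no evidence and none is given. Of 30 such genes 28 fell in WT cells (28 adjusted over the list alone), median -1.09, and 27 fell and 1 rose in KO cells (27 and 1 adjusted over the list alone), median -1.19. Without those 5 the medians were -0.78 and -1.02. At 6 h the medians were -0.66 and -0.98 (-0.59 and -0.77 without the 5), and 13 of 30 differed downward between genotypes (16 adjusted over the list alone), median -0.38 (-0.23 without the 5). A hypothesis is that the mock cells moved: the list rose by a median of 1.15 in WT and 1.32 in KO mock cells between 1 and 3 h, against 0.13 and -0.09 in stimulated cells (0.94 and 1.16 against 0.13 and 0.03 without the 5). The fall at 3 h may therefore reflect a rise in mock cells that stimulated cells did not show. Whether oxygen in the wells, its use by the cells or a direct effect of the PAMP RNA lies behind it was not tested.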
